A study of Mus musculus with 10 samples.

How the data were processed

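The series holds RNA-seq of brown preadipocyte cultures of the LSL-K4M and Mll3/4SET lines, mock or 4OHT, and ChIP-seq of H3K4me1 and H3K27ac with input DNA in LSL-K4M. Samples were grouped by line, assay, treatment and stage from their labels: 4 RNA groups and 6 ChIP or input groups, each of 1 library. No values of the ChIP and input libraries were used here. Per the labels' protocols, total RNA was taken with Trizol, mRNA was selected with a magnetic bead kit, and libraries were made by Illumina's usual steps; whether the counting used strand, and which aligner and counter were used, is not given in the sources used here. The submitters' processing notes name the mouse build mm9 and the tool SICER, with no version.

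The values of each line were deposited in a table of its own. Per the file headers, each table gives the read count and the RPKM (reads scaled to transcript length and library size) of the mock and the 4OHT library for each RefSeq transcript. The deposited counts were whole numbers and the deposited RPKM were proportional to them, with 1 factor between the libraries of a table (0.938 in the LSL-K4M table and 1.03 in the Mll3/4SET table, RPKM per read of 4OHT over mock). Per the file headers, the tables also hold the authors' ratio of mock to 4OHT; every ratio matched (mock RPKM + 0.001)/(4OHT RPKM + 0.001) within a relative tolerance of 1e-06. Another deposited column, of the unit kind other, is headed as expressed; in 100.0% of rows it equalled the number of libraries of that table at 1 RPKM or more. The authors' ratio and the expressed column were not used for any comparison here. No per-sample column of another series was found in the tables (0 columns left unused).

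The tables list 29082 transcripts under 22835 gene names, and 3906 names have more than 1 row. Isoforms of a gene share reads, so for each name the transcript with the highest mean RPKM of the 4 libraries was used. Names are those of the tables. Current symbols in brackets come from the RefSeq accession, matched to a list of assembly GRCm38.p6 for 98.0% of names; since that is another build than mm9, no coordinates are printed and it served only for names and for which genes are neighbours. Reads that fit near-identical copies may have been split or lost in the authors' counting, so genes with such copies (H3f3a, Gapdh, Pgk1, histone genes) are uncertain, and overlapping or antisense genes cannot be told apart where strand was not used.

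For each line the 4OHT library was set against the mock library as log2((4OHT RPKM + 1)/(mock RPKM + 1)) among genes at 1 RPKM or more in the higher library. With 1 library per group no test across replicates exists. Genes were counted as lower or higher by a fixed size of 2-fold. Ratios of named genes are ratios of RPKM with the exact conditional binomial 95% interval of the reads, which covers counting error only, since the reads carry no molecular identifiers; a gene with 0 reads in a library is given as a bound against 3 reads. Pearson and Spearman correlations and overlaps are across genes, with n1 × n2 / N for independent lists. The 23 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. A list is given by its members at 2-fold or more, its median, and the percentile of that median among 10000 random lists of equal size drawn from 20 bins of mean expression, as a description of these libraries. Where an interval stands beside a list median, it is a bootstrap over the members, which are not replicates. Members with 0 reads in a library occurred in 2 of the 46 list medians, and setting them to 3 reads moved no median.

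Named genes are the targeted and H3.3 genes, the 10 lowest and 10 highest genes of each line at 10 RPKM or more, up to 4 members of each list with the largest differences, genes at 2-fold or more in opposite directions (up to 5 per direction, at 10 RPKM or more in both lines), and Pparg, Cebpa, Fabp4, Adipoq, Ucp1, Cidea, Ppargc1a and Prdm16. Predicted loci and small RNA genes were left out of the ranked and opposite parts. Mock against mock used the same scale and size; its named genes lie outside this rule. Not every gene under this rule is printed, and 1 list member under it is not reported here.

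The size rule was tested on data simulated for 11700 genes of the LSL-K4M and 11680 genes of the Mll3/4SET comparison, with counting error alone. In the LSL-K4M simulation 18 of 11500 unchanged genes were called, and of 50 genes each, 98% of 3-fold higher, 78% of 3-fold lower, 100% of 4-fold higher and 90% of 4-fold lower genes were recovered. In the Mll3/4SET simulation 24 of 11480 unchanged genes were called, with the same shares recovered. Variation between cultures is not part of that. Other settings tried were pseudocounts of 0.1 and 0.001, no filter on low values or a minimum of 5 RPKM, median-ratio and upper-quartile scaling, scaling to the reads of genes under the 2-fold limit in both lines, leaving out names with several rows, a 3-fold size rule, and random lists not matched on expression. The pseudocount of 0.001 and the scaling to genes under the limit were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.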

Results

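The study asked whether histone H3.3 carrying a lysine-to-methionine change at position 4 (H3.3K4M) acts on the H3K4 methyltransferases MLL3 and MLL4 during adipogenesis. Cells were mouse brown preadipocytes from the interscapular brown fat of newborns, immortalised with SV40 large T antigen. In the LSL-K4M line, 4-hydroxytamoxifen (4OHT) activates a CreER recombinase, which by the design in the line's name (lox-stop-lox) removes a stop cassette and switches on H3.3K4M. In the Mll3/4SET line the same drug deletes a floxed part of Mll3 and the SET domain of Mll4, which is the catalytic domain. Mock cultures did not receive 4OHT. The inducing mix held dexamethasone (2 μg/ml), indomethacin (0.125 mM), IBMX (0.5 mM), T3 (1 nM) and insulin (0.02 μM). RNA was sequenced from 1 library for each line and treatment, 4 libraries in all, labelled as mature adipocytes of day 7. The titles of both 4OHT libraries say day 0, while their stage label and the headers of the tables say day 7, so day 7 was used here and the date stays in doubt. The 6 ChIP-seq and input libraries of day 4, all from LSL-K4M, were not analysed here. Summed over 1 transcript per gene, the reads were 15209600 in LSL-K4M mock, 16719700 in LSL-K4M 4OHT, 15420500 in Mll3/4SET mock and 15350700 in Mll3/4SET 4OHT. There were no replicates, so no difference below has a replicate check and no p-value is given. Genes are called lower or higher at 2-fold or more on the log2(RPKM + 1) scale, which understates the difference of weakly expressed genes. Intervals beside ratios of RPKM are exact 95% intervals that cover counting error only, and a test on the reads of 2 libraries compares those libraries, not the conditions.

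Mll3 and the gene for MLL4, which the Mll3/4SET model acts on, and the genes encoding H3.3 stayed under the 2-fold limit. Median log2 differences over these 4 genes were -0.07 (percentile 27.1 among random lists) in LSL-K4M and -0.40 (percentile 4.40) in Mll3/4SET. Mll3 was at 5.17 RPKM in LSL-K4M mock and 4.09 in LSL-K4M 4OHT, and at 7.48 and 5.46 in the Mll3/4SET libraries, 1.37-fold lower (1.29 to 1.45) with 4OHT in the latter. The gene for MLL4, listed as Mll2 in the tables (current symbol Kmt2d), was at 9.31 and 10.2 RPKM in LSL-K4M and at 13.6 and 12.2 in Mll3/4SET. Of the genes encoding H3.3, H3f3b was at 166.1 and 162.0 RPKM in LSL-K4M and at 212.5 and 132.3 in Mll3/4SET, 1.61-fold lower (1.55 to 1.66) with 4OHT. H3f3a was at 19 and 17.6 RPKM in LSL-K4M and at 20.7 and 15.3 in Mll3/4SET; near-identical copies of it in the genome make its count uncertain. These values do not check the genotypes. A read count over a whole transcript does not show whether a few exons were deleted, and the tables hold no row for the H3.3K4M transgene. The other H3K4 methyltransferases and shared complex subunits, 11 measured genes, had median log2 differences of 0.09 in LSL-K4M and 0.07 in Mll3/4SET, and none reached 2-fold. Both medians turned slightly negative under median-ratio scaling (-0.05 and -0.05). Men1, which encodes a subunit of the MLL1 and MLL2 complexes, was 1.42-fold (1.28 to 1.58) and 1.44-fold (1.29 to 1.60) higher, while the H3K27 demethylase gene Kdm6a was 1.46-fold (1.3 to 1.63) and 1.3-fold (1.17 to 1.45) lower. None of 16 enhancer coactivators and H3K4 or H3K27 demethylases reached 2-fold in either line, with medians of -0.04 and -0.05; Kdm6b had the largest difference, 1.44-fold (1.35 to 1.54) and 1.78-fold (1.69 to 1.88) lower.

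In the LSL-K4M line the 4OHT library had lower levels of nearly all adipocyte genes and higher levels of contractile genes than the mock library. Pparg, the nuclear receptor that drives fat cell differentiation, was at 133.8 RPKM in mock and 22.9 with 4OHT, 5.84-fold lower (5.45 to 6.27), and its partner Cebpa was 3.09-fold lower (2.97 to 3.22). Of 28 adipocyte markers, 26 were at least 2-fold lower and none was higher. Fabp4, a fatty acid carrier, was at 4099 and 1066 RPKM, 3.85-fold lower (3.78 to 3.92), and Adipoq, which encodes the hormone adiponectin, was 4.05-fold lower (3.90 to 4.2). Of 17 contractile and myofibroblast genes, 15 were at least 2-fold higher, led by Cnn1 (calponin), 9.71-fold (8.31 to 11.4), and including Acta2 (smooth muscle actin), at 210.9 and 1147 RPKM. In all, 754 of 12179 measured genes were lower and 641 were higher, so that 54.1% of the calls were lower. Under median-ratio scaling, which moved the median of all genes measured in both lines from 0.11 to -0.03, the calls were 976 lower and 445 higher, 68.7% lower. Scaling to the genes under the limit in both lines gave 65.6% lower. With pseudocounts of 0.1 and 0.001 the calls were nearly even, 50.5% and 50.2% lower. Genes called lower held 21.3% of the reads in the mock library and 5.85% with 4OHT.

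The genes with the lowest 4OHT to mock values in LSL-K4M, among genes at 10 RPKM or more on the log2(RPKM + 1) scale, included several known from fat cells. Rbp4, a retinol carrier, was 15.3-fold lower (12.2 to 19.4), the adipokine genes Cfd and Rarres2 were 9.97-fold (9.29 to 10.7) and 10.8-fold (8.90 to 13.1) lower, and Cox8b, a respiratory chain subunit of brown fat, was 12.8-fold lower (6.72 to 27.4). Cbr2, Itih4, Lrg1, Acp5, Apol6 and Plbd1 completed the 10, with ratios from 7.74 for Lrg1 (6.99 to 8.59) to 29.7 for Itih4 (20.1 to 45.7). The 10 highest were Igf2, an imprinted growth factor gene, at 23.4 and 260.8 RPKM and 11.2-fold higher (10.6 to 11.7), with Cnn1, Uchl1, Ptn, Actg2, the histone gene Hist1h3d, Kif1a, Timp3, Egfl6 and Cd55. Their ratios ran from 6.31 for Timp3 (6.13 to 6.50) to 11.4 for Uchl1 (8.27 to 16.1). Hist1h3d rests on 15 and 165 reads.

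Fat-making and fat-burning genes were lower together in LSL-K4M with 4OHT. Among 18 measured genes of fatty acid and triglyceride synthesis, 17 were lower, with Scd1, a fatty acid desaturase, at 5306 and 867.1 RPKM, 6.12-fold lower (6.08 to 6.16). Thrsp, Dgat2 and Agpat9 (current symbol Gpat3) were 4.51-fold (4.32 to 4.71), 4.31-fold (4.13 to 4.50) and 3.39-fold (3.08 to 3.73) lower. Of 20 measured brown fat thermogenic genes, 14 were lower and none was higher. Ucp1, the uncoupling protein of brown fat, was at 3.58 RPKM in mock and 0.0793 with 4OHT (127 and 3 reads), a ratio of 45.1 with an interval of 15.1 to 222. Cidea was 12.9-fold (6.31 to 30.8) and Ppargc1a, a coactivator of mitochondrial genes, 6.68-fold lower (5.59 to 8.04), while Prdm16, a brown fat regulator, was 2.45-fold lower by RPKM (2.09 to 2.89) at 2.74 and 1.12 RPKM and stayed under the 2-fold limit of the log scale. Cox7a1, Kcnk3 and Cpt1b were 5.36-fold (4.21 to 6.90), 6.64-fold (6.01 to 7.34) and 6.70-fold (5.55 to 8.16) lower. Fatty acid oxidation genes were lower in 18 of 21 cases, with Acadm, Acaa2, Acadl and Cpt2 between 3.25-fold and 4.03-fold, and TCA cycle and respiratory chain genes in 21 of 35 cases, with Cs, the citrate synthase gene, 2.67-fold lower (2.59 to 2.75). The list medians were -1.97 for adipocyte markers, -2.0 for synthesis, -1.81 for thermogenic genes, -1.29 for oxidation and -1.06 for the TCA cycle and respiratory chain, each below the medians of all 10000 random lists matched on expression. The 20 adipogenic transcription factors went both ways, with 8 lower, 3 higher and a median of -0.56, also below all random lists; Srebf1 and Nr1h3, regulators of lipid synthesis, were 3.54-fold (3.46 to 3.63) and 4.83-fold (4.17 to 5.62) lower.

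Several other groups stood apart from random lists in LSL-K4M. Glycolysis and hypoxia genes were lower in 10 of 19 cases, with a median of -1.03 below all random lists, and Egln3, Pdk1, Bnip3 and Pfkl were 4.17-fold (3.67 to 4.75), 3.43-fold (3.21 to 3.67), 2.98-fold (2.69 to 3.3) and 2.64-fold (2.54 to 2.75) lower. The contractile list had a median of 1.81 and the preadipocyte and mesenchymal progenitor markers one of 0.85, both above all random lists. Of those 15 progenitor markers 5 were higher and none lower, with Twist2 2.66-fold (2.44 to 2.91) and Gata2 3.28-fold higher (2.65 to 4.09). Of 30 extracellular matrix genes, 12 were higher and 1 lower (median 0.52, percentile 99.7), with Eln (elastin) 4.89-fold (4.39 to 5.45) and Col12a1 3.60-fold higher (3.52 to 3.68), and Col6a2 2.09-fold lower (2.03 to 2.16). Of 18 p53 targets and cell cycle inhibitors, 7 were higher and 1 lower (median 0.48, percentile 99.3); Cdkn1a (p21) and Bax were 2.75-fold (2.65 to 2.85) and 2.79-fold (2.55 to 3.05) higher and Gadd45a 2.89-fold lower (2.65 to 3.15). Interferon-induced genes were lower in 4 of 21 cases (median -0.50, percentile 0.06), with Rsad2 3.51-fold (3.28 to 3.76) and Mx1 2.90-fold lower (2.48 to 3.40). The 17 genes of endoplasmic reticulum stress and amino acid response had 3 lower members (median -0.52, percentile 0.06), with Trib3 5.10-fold (4.69 to 5.56) and Chac1 3.78-fold lower (3.31 to 4.33). None of 28 cell cycle genes reached 2-fold (median -0.08, percentile 2.02, or 4.74 among random lists not matched on expression). The medians of 18 cytokines and chemokines (0.22), 21 cholesterol synthesis genes (0.05) and 18 housekeeping genes (0.16) had percentiles of 72.7, 22.2 and 50.2, and those of the last 2 lists were -0.11 and -0.00 under median-ratio scaling.

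In the Mll3/4SET line the 4OHT library had far lower levels of adipocyte genes than the mock library, and again higher contractile genes. Fabp4 was at 5119 RPKM in mock and 24.3 with 4OHT, 210-fold lower (189 to 235), and Adipoq at 167.1 and 3.22, 51.9-fold lower (41.9 to 65.0). Pparg was at 100.3 and 3.23 RPKM, 31.0-fold lower (25.9 to 37.4), and Cebpa at 158.3 and 5.82, 27.2-fold lower (24.4 to 30.4). All 28 adipocyte markers were at least 2-fold lower, with a median of -4.86. Of 17 contractile genes 11 were higher and 1 was lower, with Cnn1 9.65-fold (7.95 to 11.8), Actg2 5.87-fold (5.16 to 6.71), Acta2 5.33-fold (5.17 to 5.51) and Myl9 3.46-fold higher (3.20 to 3.75). In all, 903 of 12184 measured genes were lower and 631 were higher, so that 58.9% of the calls were lower. Under median-ratio scaling, which moved the median of all genes measured in both lines from 0.12 to -0.00, the calls were 1035 lower and 463 higher, 69.1% lower. With pseudocounts of 0.1 and 0.001 the shares were 52.8% and 51.7% lower. Genes called lower held 18.4% of the reads in mock and 3.33% with 4OHT.

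The 10 lowest named genes in Mll3/4SET were Fabp4, Gpd1, Plin1, Cfd, Cd36, Apoc1, Hp, C3, Scd1 and Plin4, most of them genes of lipid storage and handling. Plin1, which coats lipid droplets, was 197-fold lower (153 to 258), Gpd1 186-fold (155 to 227), Cd36, a fatty acid transporter, 171-fold (142 to 208), and Hp (haptoglobin) 91.8-fold lower (82.1 to 103). Apoc1 had 802 reads in mock and 0 with 4OHT, at least 260-fold lower when 3 reads are taken as the floor. The 10 highest were Uchl1, Igf2, Il1rl1, Cnn1, Kif1a, Samd5, Pmaip1, Actg2, Acta2 and Wisp1 (current symbol Ccn4). Uchl1 was 14.3-fold (11.6 to 17.9), Igf2 7.81-fold (7.56 to 8.08), Il1rl1, a receptor of interleukin 33, 9.21-fold (8.14 to 10.5) and Pmaip1, a p53 target that promotes cell death, 7.75-fold higher (6.42 to 9.41).

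Lipid synthesis genes were lower in 17 of 18 cases in Mll3/4SET, with a median of -3.0; Scd1 was 72.3-fold (70.1 to 74.5), Thrsp 49.4-fold (33.0 to 77.4) and Dgat2 27.1-fold lower (23.7 to 31.0). Of 19 measured thermogenic genes 12 were lower (median -1.22, or -2.28 with a pseudocount of 0.1), with Cox7a1 38.5-fold (22.8 to 70.9), Ppargc1a 35.2-fold (22.6 to 58.0) and Cpt1b 12.8-fold lower (9.61 to 17.3). Ucp1 had 53 reads in mock and 2 with 4OHT, a ratio of 25.8 with an interval of 6.80 to 219, and Cidea 18 reads and 1 read (17.5, 2.77 to 730). Prdm16 was at 1.73 and 1.32 RPKM, 1.31-fold lower (1.10 to 1.55). Of 21 fatty acid oxidation genes 13 were lower (median -1.19), with Acadm 7.22-fold lower (6.46 to 8.08), and of 35 TCA cycle and respiratory chain genes 12 were lower (median -0.84), with Idh3a 4.51-fold lower (4.2 to 4.85). Glycolysis and hypoxia genes were lower in 10 of 19 cases (median -1.07), with Egln3 36.4-fold lower (29.3 to 45.7). These medians and that of the adipocyte markers lay below all 10000 matched random lists. Adipogenic transcription factors had 5 lower and 1 higher member of 20 (median -0.31, percentile 0.10), and cholesterol synthesis genes 4 lower and 1 higher of 21 (median -0.38, below all random lists), with Insig1 4.77-fold (4.36 to 5.22) and Lss 4.09-fold lower (3.68 to 4.54). Cytokines and chemokines had 8 lower and 2 higher of 19 (median -0.60, percentile 0.02), with the complement gene C3 86.7-fold (80.2 to 94), Il33 49.4-fold (33.8 to 75.3), Lcn2 18.8-fold (16.7 to 21.3) and Cxcl12 8.20-fold lower (7.84 to 8.58).

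Contractile genes (median 1.38) and cell cycle genes (median 0.55) lay above all random lists in Mll3/4SET, although 1 of 28 cell cycle genes reached 2-fold, Ccnb1 at 8.26 and 18.1 RPKM. Plk1, Birc5 and Cdc20, genes of mitosis, were 2.16-fold (1.76 to 2.65), 1.96-fold (1.54 to 2.52) and 1.88-fold higher (1.61 to 2.21) by RPKM. Progenitor markers split, with 3 higher and 2 lower of 15 (median 0.48, percentile 99.3); Gata2 was 3.35-fold higher (2.65 to 4.26), while Ly6a and Pdgfra were 3.22-fold (3.03 to 3.43) and 2.43-fold lower (2.36 to 2.5). Extracellular matrix genes also split, with 5 higher and 4 lower of 30 (median 0.37, percentile 92.3), the collagen VI genes Col6a1 and Col6a2 being 5.56-fold (5.41 to 5.71) and 5.08-fold lower (4.91 to 5.26). The p53 targets and cell cycle inhibitors, a list without Pmaip1, had 1 higher and 1 lower member of 18 (median 0.29, percentile 88.05). They were Bax, at 43.8 and 95.7 RPKM, and the cell cycle inhibitor gene Cdkn2c, 3.29-fold lower (2.93 to 3.71). Interferon-induced genes had 3 lower of 21 (median -0.14, percentile 2.17), with Rsad2 5.20-fold lower (4.80 to 5.64); that median was 0.10 once genes listed more than once were left out. Genes of endoplasmic reticulum stress and amino acid response had 3 lower of 17 (median -0.15, percentile 2.67), with Ddit4 3.39-fold lower (3.17 to 3.64), and housekeeping genes had 2 higher and 2 lower of 18 (median 0.15, percentile 43.8). Gusb was 2.66-fold higher (2.37 to 2.98) and Sdha 2.22-fold lower (2.13 to 2.31) in that list, and Pgk1 and Gapdh, which have many pseudogenes, had few reads for their known abundance and are uncertain.

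Most markers of other cell types were below the limit of 1 RPKM. Of 19 skeletal muscle markers 5 were measured in LSL-K4M and 3 in Mll3/4SET, with Acta1 highest at 10.9 RPKM in LSL-K4M 4OHT; the medians were 0.10 (percentile 51.9) and 0.87 (percentile 96.9). Of 12 macrophage and leukocyte markers 4 were measured in each line (medians 0.10 and -0.33, percentiles 55.4 and 18.1), with Mpeg1 at 4.6 and 0.902 RPKM in LSL-K4M and 3.32 and 0.245 in Mll3/4SET. Of 10 endothelial markers 3 were measured in each line (medians 0.55 and 0.67, percentiles 92.2 and 94.985), with Eng, which mesenchymal cells also express, 2.29-fold (2.07 to 2.53) and 2.69-fold higher (2.45 to 2.95) with 4OHT.

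**Figure D1:**
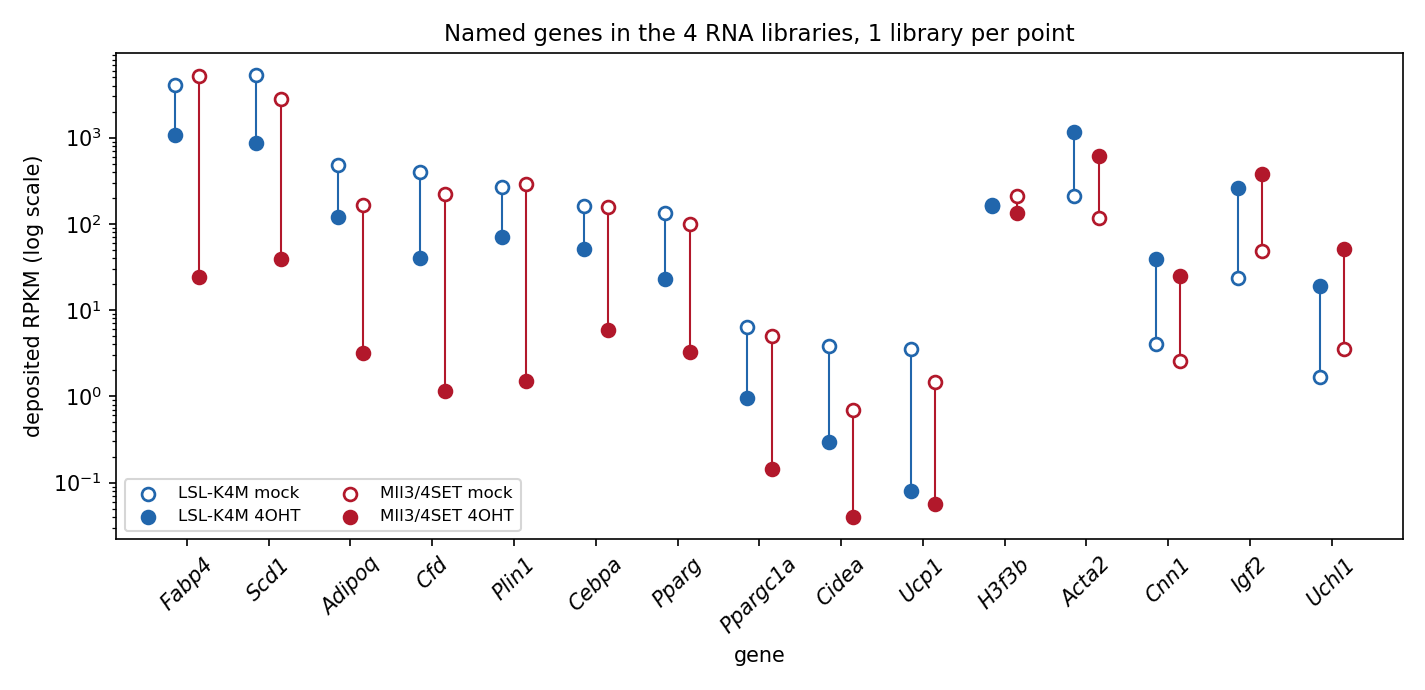
Deposited RPKM on a log axis for 15 named genes, 1 point per library (open: mock; filled: 4OHT; blue: LSL-K4M; red: Mll3/4SET), with a line joining the libraries of a line. Fabp4 lies at 4099 and 1066 RPKM in LSL-K4M and at 5119 and 24.3 in Mll3/4SET, while Acta2, Cnn1, Igf2 and Uchl1 lie higher with 4OHT in both lines.

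At the 2-fold limit the lines shared most of their lower and higher genes. Among the 11830 genes measured in both, 563 were lower in both, against 51.3 for independent lists of these sizes, and 371 were higher in both, against 30.6. The count higher in both depended on the processing, with 246 under median-ratio scaling and 593 with a pseudocount of 0.1. The shared lower genes were 80.3% of those lower in LSL-K4M and 65.1% of those lower in Mll3/4SET. For the higher genes the shares were 60.1% and 63.2%. With the 3-fold rule 234 genes were lower in both, beside 290 lower in LSL-K4M and 475 in Mll3/4SET. By that rule 62 were higher in both, beside 136 and 126. Across the 11830 genes, which are not independent replicates, the log2 differences of the lines had a Pearson correlation of 0.82 and a Spearman correlation of 0.79. The lines have separate mock libraries, so no shared control adds to this. Of the 563 shared lower genes, 430 had the larger difference in Mll3/4SET (medians -1.54 in LSL-K4M and -1.96 in Mll3/4SET), while the shared higher genes were alike (medians 1.40 and 1.36). On the log2(RPKM + 1) scale, 5 genes in LSL-K4M and 129 in Mll3/4SET were at least 8-fold lower.

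Gene groups differed in how the lines compared. All 28 adipocyte markers had the lower 4OHT to mock value in Mll3/4SET, with a median difference between the log2 values of LSL-K4M and Mll3/4SET of 3.26, above all 10000 random lists, and for synthesis genes this was 0.98, also above all. Thermogenic genes (-0.13, percentile 6.05) did not stand apart, and with a pseudocount of 0.1 their medians were -2.51 and -2.28. Fatty acid oxidation (-0.13, percentile 0.95) and TCA cycle and respiratory chain genes (-0.14, percentile 0.02) were slightly further below mock in LSL-K4M. Both lists were already lower in Mll3/4SET mock than in LSL-K4M mock, by medians of -0.59 and -0.75 in separately normalized tables. Contractile genes had the higher 4OHT to mock value in LSL-K4M in 17 of 17 cases, by a median of 0.35 (percentile 99.9), and extracellular matrix genes in 24 of 30, by 0.33 (percentile 99.97). Progenitor markers (0.48, 12 of 15 higher) and the list of p53 targets and cell cycle inhibitors (0.38, 12 of 18) also lay at percentiles of 99.99 or above. So did glycolysis and hypoxia genes (0.36, 14 of 19) and cytokines (0.75, 14 of 18). Cell cycle genes (-0.52, 27 of 28 lower) and interferon-induced genes (-0.20, 18 of 21) lay at 0.01 or below, and so did genes of endoplasmic reticulum stress and amino acid response (-0.51), which went both ways, with 9 lower and 8 higher. With 1 library per group, none of these differences between lines was tested against replicates. The lines were derived separately and differed in Xist, the RNA that silences an X chromosome (0.207 RPKM in LSL-K4M mock and 20 in Mll3/4SET mock, in separately normalized tables), so sex make-up and origin are not separated from the alleles.

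**Figure D2:**
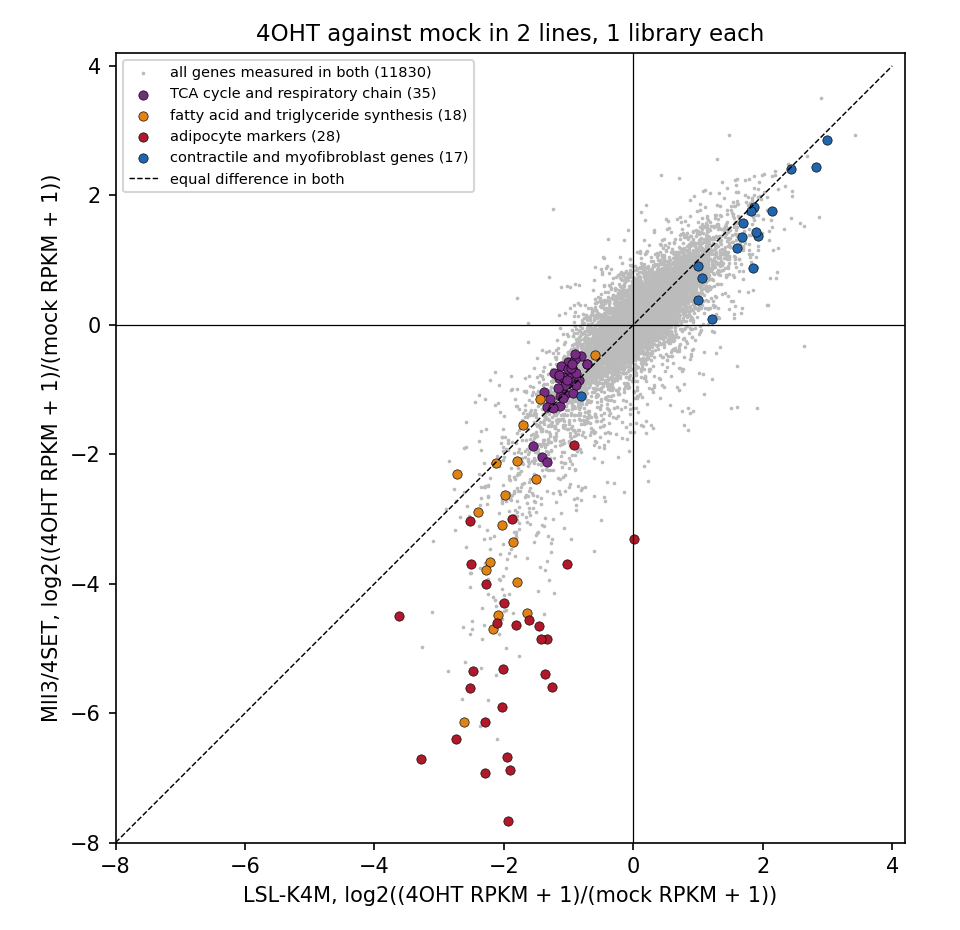
Log2 difference of 4OHT against mock in LSL-K4M (x axis) and in Mll3/4SET (y axis), 1 point per gene for the 11830 genes measured in both, with 4 gene lists coloured and a dashed line of equal difference. The 28 adipocyte markers lie below the dashed line, with medians of -1.97 and -4.86, and most contractile genes lie at the upper right.

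**Figure D3:**
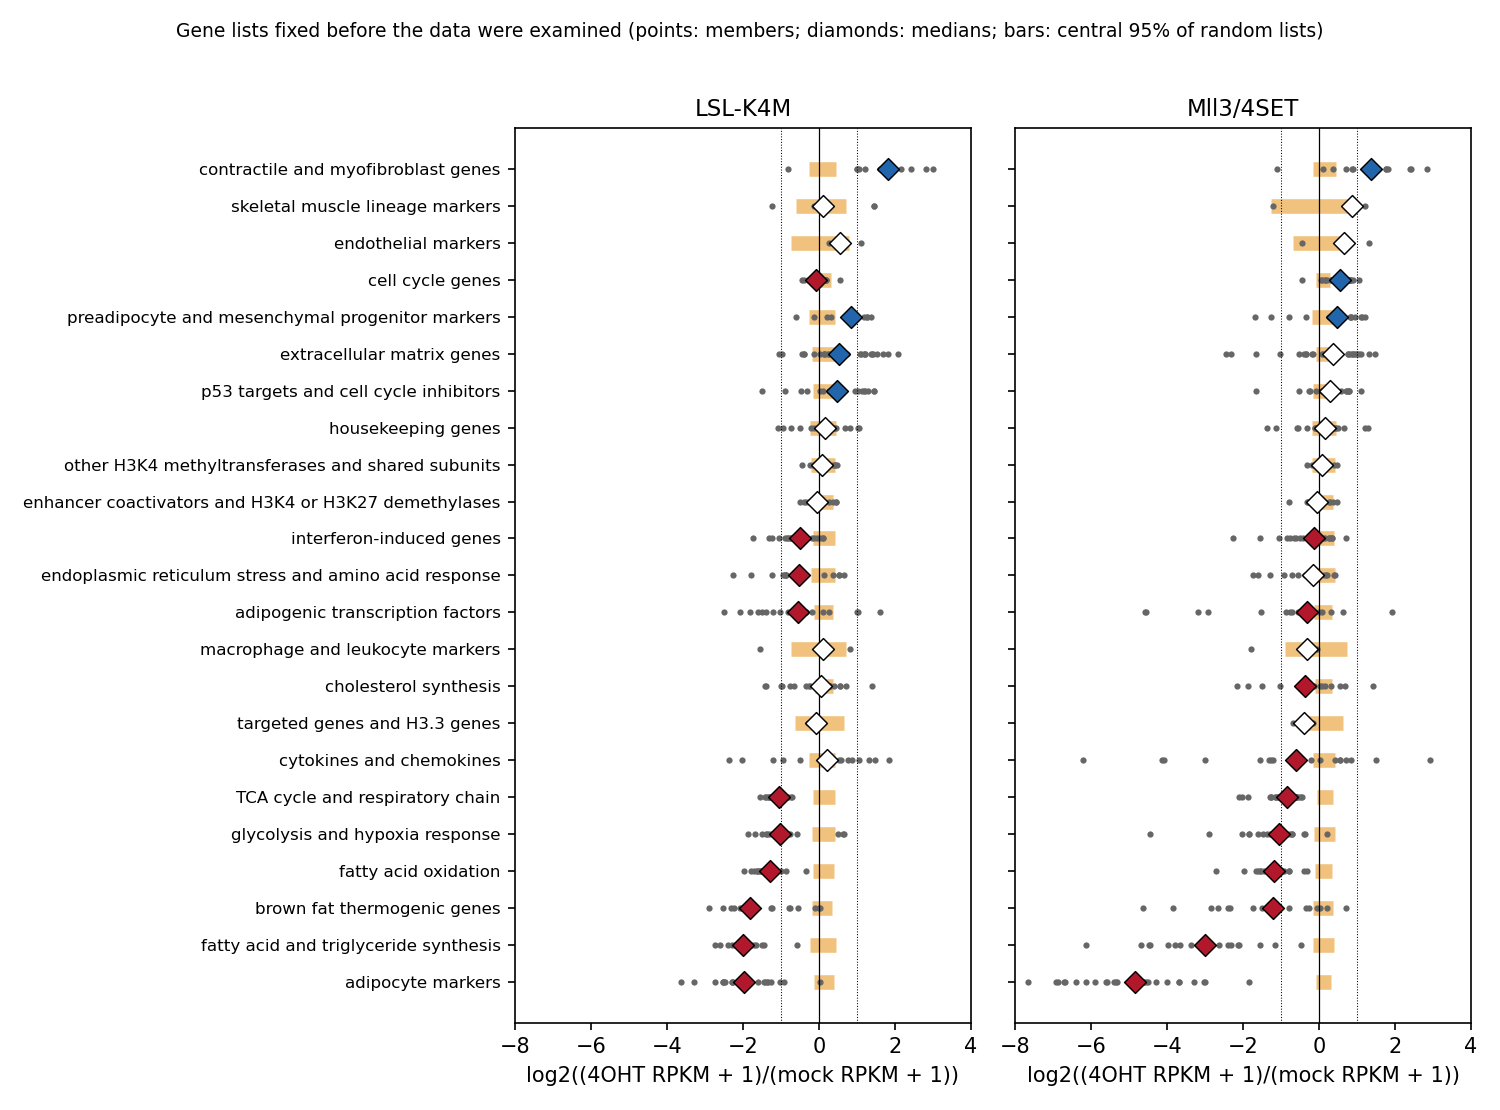
Log2 difference of 4OHT against mock for the measured members of 23 gene lists (points), their medians (diamonds; coloured where they lie outside the central 95% of random lists, white inside) and the central 95% of the medians of 10000 random lists matched on expression (bars). Dotted lines mark 2-fold; adipocyte markers lie lowest in Mll3/4SET, at a median of -4.86.

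Only 5 genes were at least 2-fold in opposite directions. Wisp2 (current symbol Ccn5), a secreted protein of mesenchymal cells, was at 37.5 and 81.0 RPKM in LSL-K4M, 2.16-fold higher (2.03 to 2.30), and at 15.9 and 7.07 in Mll3/4SET, 2.25-fold lower (1.95 to 2.61). The others are outside the rule for named genes and were picked after their values were seen. 9930013L23Rik (current symbol Cemip) was 2.91-fold higher (2.82 to 2.99) in LSL-K4M and 2.53-fold lower (2.42 to 2.66) in Mll3/4SET. The small RNA genes Mir5100, Snord11 and Snord53 had at most 7 reads in any library, so their directions were not resolved at this depth.

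The mock libraries of the lines differed before any 4OHT was given, in fewer genes than 4OHT and mock of either line, but by more for cell cycle and cholesterol synthesis genes. The 2 tables were scaled separately by the authors, so levels set across them carry that limit; the median log2 difference over 12027 measured genes was -0.00. In Mll3/4SET mock 382 genes were lower and 219 higher than in LSL-K4M mock. Cell cycle genes were lower in 14 of 28 cases (median -1.02), cholesterol synthesis genes in 12 of 21 (-1.04), fatty acid and triglyceride synthesis genes in 9 of 18 (-0.96) and TCA cycle and respiratory chain genes in 3 of 35 (-0.75), each below all random lists. Fatty acid oxidation genes (median -0.59, 3 lower and 1 higher of 21) and thermogenic genes (median -0.45, 3 lower and none higher of 20) also lay below all random lists. Adipocyte markers were lower in 5 and higher in 2 of 28 cases (median -0.44, percentile 0.03), and contractile genes lower in 2 of 17 (median -0.53, percentile 0.02). Thrsp, a regulator of lipid synthesis, was 9.39-fold lower (8.85 to 9.97) and Acly, which makes cytosolic acetyl-CoA, 5.61-fold lower (5.51 to 5.71) in Mll3/4SET mock. The genes named here for mock against mock were picked after their values were seen. The interferon-inducible gene Ifi202b was at 0.103 RPKM in LSL-K4M mock and 53.6 in Mll3/4SET mock, 519-fold higher (202 to 1905), Gbp1 15.6-fold higher (12.2 to 20.2), and the matrix gene Lum 7.09-fold higher (6.03 to 8.38).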

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

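All tests of explanations in this part were chosen after the results were seen. The differences between groups given here were not tested, since each line has 1 library per treatment. Wisp2, which encodes a secreted protein, and 9930013L23Rik (current symbol Cemip), which acts on hyaluronan, are named because 4OHT and mock differed in opposite directions in the 2 lines, with counting intervals that left out a ratio of 1 in each line. 9930013L23Rik had a log2 difference of 1.52 in LSL-K4M and -1.29 in Mll3/4SET, and Wisp2 one of 1.09 and -1.07. Cell cycle genes had medians of opposite sign, -0.078 in LSL-K4M and 0.55 in Mll3/4SET. So did cytokines and chemokines, 0.22 (-0.23 to 0.81) and -0.60 (-1.32 to 0.55), whose intervals over members both include 0. Members of the latter list went both ways, with 4 higher and 3 lower of 18 in LSL-K4M and 2 higher and 8 lower of 19 in Mll3/4SET. C3 was lower in both lines, with log2 differences of -2.37 and -6.21. Cell cycle genes were already lower in Mll3/4SET mock than in LSL-K4M mock, by a median of -1.02 in separately normalized tables. Cytokines and chemokines had a median of 0.42 (-0.03 to 0.59) in that comparison, with 2 of 19 higher in Mll3/4SET mock and none lower. No explanation was tested for these 4 results.

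Adipocyte genes were lower and contractile genes higher in both 4OHT libraries. If reads freed by abundant lipid genes had made all other genes look higher, the median of all genes would have risen with the contractile median. Over genes measured in both lines it was 0.11 in LSL-K4M and 0.12 in Mll3/4SET, against contractile medians of 1.81 and 1.38. These values argue against freed reads as the whole cause. Scaling to the reads of genes under the 2-fold limit was also predicted to bring the contractile median near 0. It was 1.69 (bootstrap interval 1.09 to 1.83) in LSL-K4M and 1.28 (0.77 to 1.65) in Mll3/4SET. The genes used for that scaling were picked for small differences, which limited the possible shift, so its result decides nothing. Whether the 4OHT libraries were taken at day 0, as their titles say, or at day 7 cannot be told apart, because 0 libraries are given as day 0 by their stage and could serve as reference. At 10 RPKM or more were 22 of 28 adipocyte markers in LSL-K4M 4OHT and 4 of 28 in Mll3/4SET 4OHT. An effect of H3.3K4M or of the loss of MLL3 and MLL4 activity on differentiation stays open beside a difference in day, and so does an effect of 4OHT itself, since no line without the alleles was given the drug.

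With 4OHT, adipocyte markers were less far below mock in LSL-K4M than in Mll3/4SET. If the markers had started lower in LSL-K4M and so had less far to fall, they would have been lower in its mock library. Of 28 markers 19 were higher there than in Mll3/4SET mock, with a median log2 difference of 0.44 (bootstrap interval over markers 0.03 to 0.75), in separately normalized tables. The other markers, Fabp4 among them, were not higher. Markers are not replicates, so that interval does not show that the mock cultures differ. If some LSL-K4M cells did not respond to 4OHT, genes switched off in the others would keep about the same share of their mock level. The 61 genes at least 16-fold lower in Mll3/4SET were used for this. Some of them were not off there, such as Scd1 at 38.8 RPKM with 4OHT. Over these 61 genes the 90th percentile of that share in LSL-K4M was 2.43 times the 10th, against 3.51 for the same genes between the mocks. A mixed culture and a weaker effect in every cell cannot be told apart, because no table holds single cells or replicates; the sex make-up and origin of the lines also stay open, untested.

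Hist1h3d, a replication-dependent H3 gene, was among the 10 highest genes in LSL-K4M 4OHT, with 15 and 165 reads. The other 44 measured histone cluster genes had a median of -0.76 (bootstrap interval over genes -0.84 to -0.66), with 2 above 0. The summed reads of the 5 measured neighbours of Hist1h3d were at 0.489 (0.430 to 0.556) of mock. These values argue against more reads for the whole class and against reads from neighbours. The class also differed between the mocks, with 35 of 44 lower in Mll3/4SET mock (median -1.67), in separately normalized tables. Reads of the H3.3K4M transgene may have been counted on Hist1h3d; in Mll3/4SET, which carries no such transgene, the ratio was 3.59 (0.684 to 35.5). This cannot be told apart from higher expression of the gene, because 2 and 7 reads leave that interval wide and the transgene's sequence is not in the sources used here. No biological explanation was tested.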

How the results depend on the processing

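The pseudocount of 0.001 and the scaling to genes under the limit in both lines were chosen after the results were seen. Counts within 1.5 times of the reported one, correlations within 0.1 of it, and medians and genes within their intervals are taken as not moved, a wide limit for counts. By it 69 of 90 counts and correlations had not moved and 21 had; of list medians 347 had not, 17 had and 1 reversed, and of named genes' values 2217 had not, 818 had and none reversed. Except where stated, the cause was not tested.

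With a pseudocount of 0.1, 1018 genes were higher in LSL-K4M, 1013 in Mll3/4SET and 593 in both, and between the mocks 615 were lower and 371 higher. Medians were -5.98 for adipocyte markers in Mll3/4SET, -2.51 for thermogenic genes in LSL-K4M (-2.28 in Mll3/4SET) and 1.63 for muscle markers in Mll3/4SET. With 0.001 the counts were 1075, 1083, 631, 650 and 403, the correlation between lines was 0.72, and the medians were -6.46, -2.58 and 1.69, with -2.55 for thermogenic genes in Mll3/4SET. Lower genes numbered 1040 in LSL-K4M and 1134 in Mll3/4SET with 0.1, and 1084 and 1161 with 0.001, so lower and higher calls were closer to even. A smaller constant widens differences of weakly expressed genes by construction.

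Median-ratio scaling left 246 genes higher in both lines. It gave medians of -1.22 for TCA cycle and respiratory chain genes, 0.69 for progenitor markers and -0.24 for cell cycle genes in LSL-K4M, and -0.18 for coactivators in Mll3/4SET. Upper-quartile scaling gave -1.14 for the TCA cycle and respiratory chain in LSL-K4M. Scaling to genes under the limit gave -1.18 for that list and -0.20 for cell cycle genes in LSL-K4M, and -0.15 for coactivators in Mll3/4SET.

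Without a filter on low values the rank correlation was 0.679, and the medians of macrophage markers in Mll3/4SET and endothelial markers in LSL-K4M were 0 and 0. No count of genes can differ there, because 2-fold with a pseudocount of 1 needs 1 RPKM. Leaving out genes listed more than once reversed the median of interferon-induced genes in Mll3/4SET to 0.10. With a minimum of 5 RPKM every count was smaller, within 1.5 times: 620 lower and 501 higher in LSL-K4M, 689 and 472 in Mll3/4SET, and 306 and 147 between the mocks. The 3-fold rule gave, by construction, smaller counts: 290 lower and 136 higher in LSL-K4M, 475 and 126 in Mll3/4SET, 234 and 62 shared, and 95 and 34 between the mocks. Among random lists not matched on expression, percentiles were 99.5 for extracellular matrix and 98.4 for muscle markers in Mll3/4SET and 4.74 for cell cycle genes in LSL-K4M.

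The authors' deposited ratios are mock over 4OHT, so a ratio of at least 2 means lower with 4OHT. They count transcripts, not genes, and use an added constant of 0.001. In LSL-K4M 1433 transcripts had ratios of at least 2 and 1472 of at most 0.5, among 16613. In Mll3/4SET these were 1541 and 1512, among 16603. The expressed columns place these transcripts at 1 RPKM or more in at least 1 library. Lower and higher transcripts were thus nearly even in both lines. The main gene calls had more lower than higher genes, 754 and 641 in LSL-K4M and 903 and 631 in Mll3/4SET. Gene-body values could not be tried, since the files hold none. No paired analysis was possible within a line because each has 1 library per treatment. A shared 4OHT effect with the line as a block was not fitted, since it would take different alleles for replicates. Depth limits genes with few reads: Ucp1 had 3 and 2 reads in the 4OHT libraries, and its ratios had intervals of 15.1 to 222 and 6.80 to 219.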

Other observations

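All lists and genes in this part were chosen after their values were seen, and no explanation was tested for them. Of 20 measured imprinted genes, 9 were higher and none lower with 4OHT in LSL-K4M (median 0.92), and 6 higher and none lower in Mll3/4SET (median 0.75). H19, a noncoding RNA next to Igf2, was at 172.4 and 868.0 RPKM in LSL-K4M and 376.8 and 1055 in Mll3/4SET. Of 19 genes of serine synthesis and other ATF4 targets, 5 were lower and none higher in LSL-K4M (median -0.80), against 1 lower and 2 higher in Mll3/4SET (median 0.21), and 18 of 19 had the lower 4OHT to mock value in LSL-K4M. Both lists already differed between the mocks, in separately normalized tables: 4 of 19 measured imprinted genes (median 0.43) and 4 of 19 serine and ATF4 genes (median 0.52) were higher in Mll3/4SET mock, and none was lower. Cth, which makes cysteine, was at 14.1 and 7.07 RPKM in LSL-K4M and 31.5 and 49.3 in Mll3/4SET.

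Xist, the RNA that silences an X chromosome, was at 0.207 and 0.124 RPKM in the LSL-K4M libraries and 20 and 15.3 in the Mll3/4SET libraries, which are separately normalized tables. The Y-linked gene Ddx3y was at 15.5 and 17.8 RPKM in LSL-K4M and 25.3 and 18.5 in Mll3/4SET. Ifi202b was at 53.6 and 53.5 RPKM in Mll3/4SET, while LSL-K4M mock and 4OHT had 4 and 0 reads.

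Klf4, a transcription factor of early adipogenesis, was higher with 4OHT in both lines, at 11.7 and 37.8 RPKM in LSL-K4M and 16.6 and 65.3 in Mll3/4SET. Over the 61 genes at least 16-fold lower in Mll3/4SET with 10 RPKM or more in both mocks, the median share of mock RPKM left with 4OHT was 21.1% in LSL-K4M and 1.60% in Mll3/4SET. In LSL-K4M that share ran from 6.53% for Rbp4 to 42.6% for Lcn2. The genes were picked by their fall in Mll3/4SET, so the small share in that line was fixed by the choice. The shares therefore do not measure how far the lines differ.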
